A study of Gossypium barbadense and Gossypium hirsutum with 4 samples.

How the data were processed

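RNA of cotton fibre at 11 days post-anthesis was hybridized to 4 Affymetrix cotton arrays with a biotin label, 2 of VH8-4602 and 2 of Guazuncho 2. The genotype of each array was taken from the labels, and replicate numbers only name the arrays and pair none of them. The values the authors deposited were on a log2 scale, which was inferred from their range of 1.20 to 16.16. They were made with GCRMA, per the submitters' processing notes, with the version not given in the sources used here. GCRMA subtracts background by probe composition, sets the distributions of the arrays equal and combines the probes of a probe set, so small values are compressed towards a floor and a shift shared by most transcripts is removed.

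Values were used as deposited. Of 24132 probe sets, 103 AFFX controls were left out, and 12603 of the other 24029 entered with a log2 value above 4 on at least 2 of the 4 arrays, which left 11426 untested. Negative controls were 74 probe sets taken by their IDs (RPTR, Tag or TrpnX), and hybridization controls were 27 (BioB, BioC, BioD or cre). A further RPTR probe set was left out of the negative controls after its values were seen, as it averaged 15.26 in VH8-4602 and 15.06 in Guazuncho 2. It stayed among those tested and did not pass the test (limma adjusted p = 0.189). VH8-4602 minus Guazuncho 2 was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) with no covariates. The fit had 2 residual degrees of freedom and 2.56 prior degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

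The test, the filter, the groups by ID prefix, 25 gene lists and the rule for named probe sets were fixed before the data were examined. The rule named the 10 largest differences per direction among probe sets with a named gene, up to 4 members of each gene list, and at most 2 probe set IDs per direction where no table names the genes. The tables used here do not pair probe sets with genes, so the last part applied, and none of the 25 gene lists could be filled or tested. Groups by ID prefix were tested with camera at a preset correlation of 0.01 and with an estimated one, with fry, and against 10000 random sets matched on mean signal in bins. Control transcripts were read from AFFX probe sets added to the fit.

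The test was checked on simulated data with the means of the 12603 probe sets. Their spread was normal and drawn at random from the prior that limma fitted to the real arrays. The simulated data thus follow the model of the test, with a spread that does not depend on signal. Of 50 probe sets changed by 0.5 on the log2 scale it recovered 0%, of 50 changed by 1 it recovered 40%, of 50 changed by -1 it recovered 44%, and of 50 changed by 2 it recovered 90%. It called 0 of 12403 unchanged probe sets. Only 87 probe sets were called in all, and a call depends on how many others differ.

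Other settings fixed at the same time were no filter, a filter at log2 6, quantile normalization, median centring, an intensity trend or a robust prior in limma, no moderation, each array left out, a log2 difference of at least 1, an adjusted p under 0.01, each prefix fitted alone, an estimated correlation and fry. Settings chosen after seeing the data were hybridization controls set equal, a filter above the negative controls, 1 probe set per ID number, and control probe sets added to the fit.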

Results

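Gene expression was measured in cotton fibre at 11 days post-anthesis, in plants of 2 genotypes grown in a glasshouse without treatment. VH8-4602 is a line of Gossypium barbadense and Guazuncho 2 a line of Gossypium hirsutum, and each was read on 2 one-colour Affymetrix cotton arrays. The comparison asked which probe sets differed in signal between the fibres of the genotypes. Each array held 24132 probe sets, of which 24029 lacked the AFFX prefix of array controls. Between 51.1% and 51.6% of those read above log2 4 on each array, and 74 negative control probe sets had medians of 2.02 to 2.07 with no single value above 3.64. A further probe set with a negative control ID read above log2 15 on every array and was for that reason left out of them. Arrays give no read depth, and their number limited the precision. The labels do not say whether the replicate samples came from separate plants, so p-values measure only the spread between these samples, which may be technical.

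Replicate arrays of 1 genotype were far closer to each other than arrays of different genotypes. Over the 12603 probe sets that passed the filter, the log2 signals of the VH8-4602 replicates correlated with r = 0.995 and those of the Guazuncho 2 replicates with r = 0.995, while the 4 pairs of different genotypes gave 0.915 to 0.919. The SD of the differences was 0.27 within VH8-4602 and 0.27 within Guazuncho 2, against 1.09 to 1.11 between them. Only 129 probe sets differed by more than 1 on the log2 scale between the VH8-4602 replicates and 101 between those of Guazuncho 2, against 2250 to 2392 across genotypes. These correlations run across probe sets, which are not independent replicates.

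Fibre of VH8-4602 and Guazuncho 2 differed in signal in a large share of the probe sets tested, mostly by small amounts. Of the 12603 probe sets tested, 5791 (45.9%) differed, with 3162 higher and 2629 lower in VH8-4602. The median size of the log2 difference among them was 0.80, or 1.74-fold. Among all tested probe sets the 5th and 95th percentiles were -1.61 and 1.37, around a median of 0.05. Both arrays of 1 genotype lay above both arrays of the other in 9883 probe sets (78.4%), where chance gives 33.3%. The test was limma with Benjamini-Hochberg adjusted p under 0.05, and the median SE of a difference was 0.11. With limma's moderation left out, 1875 probe sets differed, 1019 higher and 856 lower, and 1792 of them were among the 5791. A difference in signal can reflect the level of a transcript or how well the probes match it in each genotype, and these were not separated.

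The balance between higher and lower probe sets depended on the scale on which arrays were set equal. The 27 hybridization control probe sets, which read RNA added in fixed amounts, averaged 11.24 ± 0.01 in VH8-4602 and 10.95 ± 0.14 in Guazuncho 2 (SD, n = 2), and all 27 were higher in VH8-4602. With these controls set equal, the median of all tested probe sets moved to -0.24, and 1557 probe sets were higher and 4074 lower in VH8-4602. The share higher was then 27.7%, against 54.6% on the deposited scale. The size of this shift rests on few arrays. The offset of the controls was 0.29 with all arrays, 0.20 without Guazuncho 2 replicate 1 and 0.39 without Guazuncho 2 replicate 2. Directions below refer to the deposited scale. On that scale the median difference of all tested probe sets was 0.04 without VH8-4602 replicate 2, against 0.05 with all arrays.

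**Figure D1:**
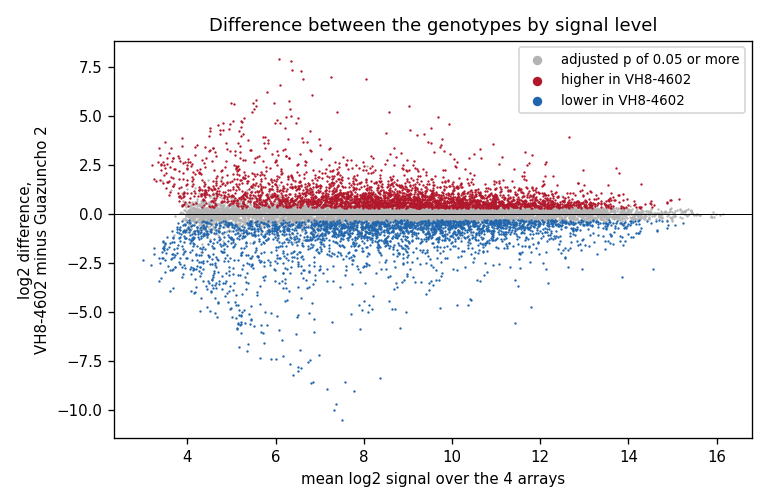
Difference in log2 signal between VH8-4602 and Guazuncho 2 (vertical axis) against the mean log2 signal over the 4 arrays (horizontal axis), 1 point for each of the 12603 probe sets tested. Red points were higher and blue points lower in VH8-4602 at an adjusted p under 0.05. The far points reach further down, to -10.51, than up, to 7.91. Both of these compare with a genotype at or below the negative controls, so their exact size depends on the floor of the values.

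Large differences were more often in the direction of lower signal in VH8-4602. At 2-fold or more, 1029 probe sets were higher and 1142 lower in VH8-4602. At 8-fold or more, 122 were higher and 219 lower, so that 64.2% were lower (95% exact interval 58.9 to 69.3, exact binomial test against equal numbers, two-sided p = 1.67e-07). With the hybridization controls set equal, 94 were higher and 273 lower at 8-fold or more. On the deposited scale, among Ghi and GhiAffx probe sets 201 were lower and 106 higher, and among Gra and GraAffx 17 were lower and 16 higher, or 51.5% lower (95% exact interval 33.5 to 69.2), with no difference between these groups called (Fisher's exact test, two-sided p = 0.128). At 64-fold or more, 10 were higher and 31 lower. The binomial test treats probe sets as independent, which those of 1 transcript are not; with 1 probe set per ID number and direction, 213 were lower and 117 higher.

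**Figure D2:**
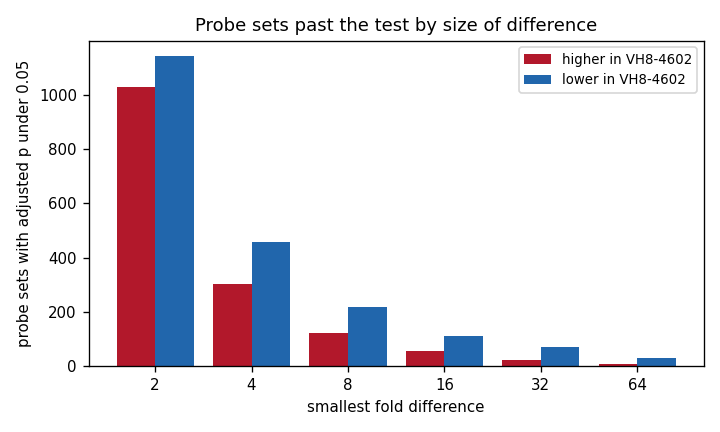
Number of probe sets with an adjusted p under 0.05 (vertical axis) at or above each fold difference (horizontal axis), higher in VH8-4602 in red and lower in blue. The bars go from 1029 higher and 1142 lower at 2-fold to 10 higher and 31 lower at 64-fold.

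Some probe sets gave signal above the array background in 1 genotype alone. In 97 probe sets both VH8-4602 arrays lay at or below their highest negative control while both Guazuncho 2 arrays read above log2 6. In 32 probe sets the opposite held. The highest negative control was 3.64 and 3.46 on the VH8-4602 arrays, and 3.23 and 3.33 on those of Guazuncho 2. The bar was thus looser in VH8-4602, which favours the count of 97, and a bar common to all arrays was not tried. All 129 passed the test, which their selection for a wide gap on the same arrays made nearly certain. Signal at background does not show that a transcript was absent, since the match of the probes to the transcripts of each genotype was not measured. Of the 97, 58 had the ID prefix Ghi and 32 the prefix GhiAffx. The probe set IDs were not paired with genes in the tables used here, so these probe sets are described by ID prefix.

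The probe sets with the widest differences were at background in 1 genotype. Gra.207.1.A1_s_at read 12.76 ± 0.02 in Guazuncho 2 and 2.25 ± 0.12 in VH8-4602 (SD, n = 2), a log2 difference of -10.51 with an SE of 0.10 (limma adjusted p = 2.83e-05). Ghi.8424.1.A1_at read 12.31 ± 0.11 in Guazuncho 2 and 2.33 ± 0.00 in VH8-4602, a difference of -9.98 with an SE of 0.10 (limma adjusted p = 2.83e-05). In the other direction, GhiAffx.41577.1.S1_s_at read 10.04 ± 0.85 in VH8-4602 and 2.12 ± 0.01 in Guazuncho 2, a difference of 7.91 with an SE of 0.41 (limma adjusted p = 0.000463). Ghi.3621.1.S1_at read 10.25 ± 0.38 in VH8-4602 and 2.44 ± 0.00 in Guazuncho 2, a difference of 7.80 with an SE of 0.20 (limma adjusted p = 9.20e-05). The dim genotype lay at or below the negative controls, so the fold is a bound set by the highest negative control of each array. Gra.207.1.A1_s_at was at least 593-fold and Ghi.8424.1.A1_at at least 432-fold lower in VH8-4602, and GhiAffx.41577.1.S1_s_at was at least 108-fold and Ghi.3621.1.S1_at at least 125-fold higher. The bound of GhiAffx.41577.1.S1_s_at was 71.3-fold without VH8-4602 replicate 2 and 165-fold without VH8-4602 replicate 1.

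Above a mean log2 value of 4, differences of at least 2-fold grew rarer with signal. Between mean log2 values of 4 and 6, 42.3% differed and 25.8% differed by at least 2-fold. Between 8 and 10 these shares were 48.6% and 15.3%, and between 12 and 14 they were 39.5% and 7.75%. Above 14, 50 of 234 probe sets differed (21.4%) and 4 differed by at least 2-fold. At mean values up to 4, 165 of 197 differed (83.8%) and 67.5% differed by at least 2-fold, but the filter admits such dim probe sets largely where 1 genotype is higher, and so shapes the low end. The mean runs over both genotypes, so a probe set at background in 1 genotype falls in a dimmer bin than its brighter genotype would give. This may add to the trend and was not separated from it.

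Probe sets grouped by ID prefix differed in how many members passed the test, and their median differences lay close to 0. Of the prefix Ghi, 2957 of 6375 probe sets differed (46.4%, 1550 higher and 1407 lower in VH8-4602), and of GhiAffx, 2072 of 4300 (48.2%, 1208 higher and 864 lower). Of Gra, 400 of 1001 differed (40.0%, 196 higher and 204 lower), and of GraAffx, 326 of 843 (38.7%, 189 higher and 137 lower). Of GarAffx, 25 of 53 differed, and of GbaAffx, 8 of 27. Ghi and GhiAffx together had 47.1% and Gra and GraAffx 39.4% (Fisher's exact test, two-sided p = 6.44e-10). The central 95% of random sets matched to the latter on mean signal ran from 44.1% to 48.4%, with the lowest at 42.0%. Both comparisons treat probe sets as independent, which those of 1 transcript are not. The filter also admitted 61.7% of the Ghi and 66.6% of the GhiAffx probe sets on the array, but 29.2% of Gra and 23.1% of GraAffx.

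Median log2 differences were 0.03 for Ghi, 0.09 for GhiAffx, 0.01 for Gra and 0.06 for GraAffx. Among 10000 random sets matched on mean signal, the Ghi median lay at percentile 0 and the GhiAffx median at percentile 99.99, the Gra median at 3.88 and the GraAffx median at 82.1. The Ghi median thus lay below, and the GhiAffx median above, the central 95% of its random sets (0.04 to 0.06 and 0.04 to 0.07). The random sets treat probe sets as independent, while camera allows for a correlation between them. They were drawn from all tested probe sets, those of the prefix itself included. With limma's camera no shift was called, at an adjusted p of 0.679 for all 6 prefixes, and with an estimated correlation the adjusted p was 0.823. With fry, which asks whether the members of a prefix move one way on balance, adjusted p ran from 0.23 to 0.438. The mean difference of Ghi was -0.05 and that of Gra -0.04, opposite in sign to their medians. Without a filter, the shift of Ghi against the other prefixes turned from -0.04 to 0.003 and that of GraAffx from 0.01 to -0.003.

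All 3 probe sets tested with the prefix GhirRNA were higher in VH8-4602; they were singled out after their values were seen. GhirRNA.2.1.S1_s_at read 9.90 ± 0.47 in VH8-4602 and 7.93 ± 0.36 in Guazuncho 2 (SD, n = 2), a difference of 1.97 (limma adjusted p = 0.00694). GhirRNA.1.1.S1_at differed by 0.87 (limma adjusted p = 0.0213) and GhirRNA.4.1.S1_s_at by 0.66 (limma adjusted p = 0.00794). The number past the test was 2 without VH8-4602 replicate 1, without VH8-4602 replicate 2, without a filter, at an adjusted p under 0.01 and with the hybridization controls set equal, and 0 with limma's moderation left out. It was 2 with a filter at log2 6 and 4 with a filter above the negative controls, which change the probe sets tested.

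Control probe sets that carry actin, ss1 and ubq11 in their IDs read cotton transcripts at several positions along their length, and were added to the fit for this purpose after the data were seen. Actin, the protein of microfilaments, was represented by 2 designs that moved apart. Gra-actin was higher in VH8-4602 by 1.5 at the 3' end (10.34 ± 0.03 against 8.84 ± 0.33, SD, n = 2, limma adjusted p = 0.0039) and by 2.41 in the middle (limma adjusted p = 0.000248), with a 5' difference of 0.32 (limma adjusted p = 0.213). Ghi-actin gave differences of -0.15 at the 3' end (limma adjusted p = 0.246) and -0.23 in the middle (limma adjusted p = 0.111), and was lower in VH8-4602 at the 5' end, with a difference of -0.85 (limma adjusted p = 0.0184). Ghi-ss1 was lower in VH8-4602 at all 3 positions, with differences of -1.03 at the 3' end, -1.74 in the middle and -1.87 at the 5' end (limma adjusted p = 0.00243, 0.00393 and 0.0127). Ghi-ubq11 gave 0.44 at the 3' end (limma adjusted p = 0.0679) and 0.15 at the 5' end (limma adjusted p = 0.558), and the latter turned to -0.15 with the hybridization controls set equal. The 5' calls of Ghi-actin and Ghi-ss1 were lost without a filter (adjusted p = 0.0746 and 0.0694), without VH8-4602 replicate 1 (0.0727 and 0.0638) and without VH8-4602 replicate 2 (0.0858 and 0.0666). With limma's moderation left out, the calls of Ghi-actin 5' (adjusted p = 0.139), Gra-actin 3' (0.0801), Ghi-ss1 middle (0.0828) and Ghi-ss1 5' (0.135) were lost. Other settings added calls. Ghi-ubq11 3' passed with an intensity trend (adjusted p = 0.03). Its difference was 0.63 without VH8-4602 replicate 2 and 0.26 without VH8-4602 replicate 1. The Ghi-ubq11 5' difference was -0.0835 without Guazuncho 2 replicate 2. Ghi-actin in the middle passed with an intensity trend (adjusted p = 0.0303) and with the hybridization controls set equal (adjusted p = 0.0348). Gra-actin 5' passed without VH8-4602 replicate 1 (a difference of 0.56, adjusted p = 0.0439), and its difference was 0.084 without VH8-4602 replicate 2.

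The signal at the 5' end relative to the 3' end was lower in VH8-4602 for the 4 transcripts read above log2 4. The 5' minus 3' signal was -3.05 ± 0.03 in VH8-4602 and -2.35 ± 0.23 in Guazuncho 2 for Ghi-actin (SD, n = 2), and -4.24 ± 0.36 against -3.06 ± 0.40 for Gra-actin. For Ghi-ss1 it was -4.96 ± 0.13 against -4.12 ± 0.71, and for Ghi-ubq11 -1.87 ± 0.10 against -1.58 ± 0.31. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. Without Guazuncho 2 replicate 1 the difference between the genotypes shrank from -0.84 to -0.34 for Ghi-ss1 and from -0.30 to -0.08 for Ghi-ubq11, and without Guazuncho 2 replicate 2 it grew to -1.34 for Ghi-ss1 and -0.51 for Ghi-ubq11.

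**Figure D3:**
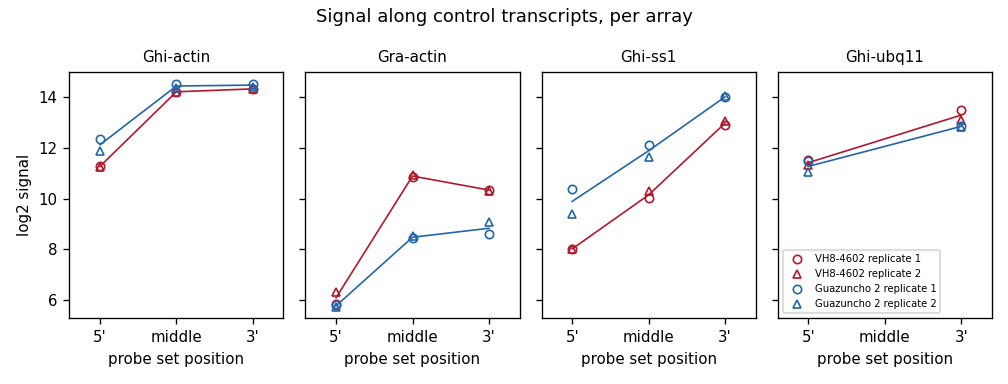
Log2 signal (vertical axis) of the probe sets at the 5' end, middle and 3' end (horizontal axis) of 4 cotton control transcripts, 1 symbol per array, VH8-4602 in red and Guazuncho 2 in blue, with lines through the genotype means. Gra-actin lies higher in VH8-4602 at the 3' end and in the middle, and Ghi-ss1 lies lower in VH8-4602 at all 3 positions.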

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

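The alternatives with hybridization controls set equal, a filter above the negative controls, 1 probe set per ID number and control probe sets added were chosen after the data were seen. Of the 5791 calls, 5598 were kept with quantile normalization, 5531 with median centring, 5625 with an intensity trend, 5750 with a robust prior, 5047 with a filter at log2 6, 4438 with no filter, 1792 with no moderation and 4180 with the hybridization controls set equal. None of the shared calls changed direction. Only quantile normalization, median centring and the hybridization controls set equal could change one, since the other settings listed leave each difference as it was. The 4 named probe sets kept their direction and their call in every alternative run for them. No paired analysis was possible because no array number in the labels is shared by the 2 genotypes, and the replicate numbers used here only name the arrays. The alternative of 1 probe set per named gene and the tests of gene lists were not run, since no table used here pairs probe sets with genes.

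With no moderation, 1875 probe sets differed, 1019 higher and 856 lower in VH8-4602, with 971 of Ghi, 677 of GhiAffx, 117 of Gra, 103 of GraAffx and 0 of GhirRNA; this test has only 2 residual degrees of freedom. A log2 difference of at least 1 left 2171, 1029 higher and 1142 lower, with 1123 of Ghi, 776 of GhiAffx, 155 of Gra and 103 of GraAffx. An adjusted p under 0.01 left 3278, 1754 higher and 1524 lower, with 1669 of Ghi, 1190 of GhiAffx, 230 of Gra and 169 of GraAffx. Both are stricter by construction. With the hybridization controls set equal, 1557 were higher and 4074 lower, and Ghi-ubq11 at the 5' end turned to -0.15; this shift moves every probe set alike. Without a filter, the shift of the prefix Ghi turned to 0.0029 and that of GraAffx to -0.0028, with camera adjusted p of 0.647 and 0.617, and the cause was not tested.

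The mean correlation within a genotype was 0.998 without a filter, 0.99466 with a filter at log2 6 and 0.99539 with a filter above the negative controls, against 0.99499. Between genotypes it was 0.97551, 0.88214 and 0.92982, against 0.91706, since the filter sets the range of signal. Leaving out 1 array at a time, with the lone array assumed to vary like the other genotype, gave 4017 to 4598 probe sets different, 2102 (without VH8-4602 replicate 2) to 2422 higher and 1879 to 2176 lower. Ghi-ubq11 at the 5' end ranged from -0.0835 (without Guazuncho 2 replicate 2) to 0.379. The signal over background limits the dim genotype of the 129 probe sets read in 1 genotype alone.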

Other observations

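All tests in this part except those with median centring and quantile normalization were chosen after the result they bear on was seen. Probe sets that share an ID prefix and number moved together: over 786 pairs the log2 differences correlated with r = 0.68 (across probe sets, which are not independent replicates), against -0.08 to 0.07 for shuffled pairs. Of 214 pairs with both members past the test, 197 had the same direction and 17 opposite directions, or 92.1% the same against 50.4% by chance.

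Probe sets that differed by at least 8-fold were more often lower in VH8-4602. Taking out the offset of the arrays that the hybridization controls show was by itself no test of whether it was the cause. These controls were higher in VH8-4602, so taking their offset out lowers every VH8-4602 value. A rise of the number lower over the number higher was thus fixed beforehand. That ratio was then 2.90, against 1.80 as deposited (254 lower and 106 higher without Guazuncho 2 replicate 1 in the offset). What the controls show is an offset opposite in direction to the pattern. All 27 were higher in VH8-4602, with an offset of 0.29 (0.20 without Guazuncho 2 replicate 1 and 0.39 without Guazuncho 2 replicate 2). An offset that raises VH8-4602 values does not make more of them lower, which argues against this offset as the cause. Other scaling of the arrays stays open: the ratio was at least 1.79 under median centring and quantile normalization, but these moved the median difference by only -0.046 and -0.0008, as GCRMA had already set the arrays equal, which is too little to decide. Compression of dim values stays open: among probe sets with a mean above log2 8 the share lower was 63.5% (95% exact interval 51.5 to 74.4), but 9 of these 74 still had a genotype at or below log2 6, and a stricter form chosen after that result, with the dimmer genotype above log2 6 and 1 probe set per ID number, gave 62.9% (49.7 to 74.8). Probes that match the transcripts of VH8-4602 less well may also account for it, and this could not be decided. Other probe sets of the same ID number moved by a median of 0.523 times the lower probe set (bootstrap interval 0.169 to 0.6, 19 ID numbers). In the other direction the median was 0.604 times for 9 ID numbers (permutation test, two-sided p = 0.579). The probe set with the widest difference of each ID number was the one compared against, which by itself lowers these ratios. A difference in expression between the genotypes is open and untested.

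The 5' signal of the 4 cotton control transcripts was lower relative to the 3' signal in VH8-4602, by a median of -0.77, which shrank to -0.44 without Guazuncho 2 replicate 1 (smallest of the 4 -0.08). At the 5' end itself the difference was -0.85 for Ghi-actin and -1.87 for Ghi-ss1, but 0.32 for Gra-actin and 0.15 for Ghi-ubq11. For Gra-actin and Ghi-ubq11 the shift thus came from a 3' signal that was higher in VH8-4602 by more. Ghi-actin and Gra-actin are both designs for actin. How well the probes at each end match the transcripts of each genotype was not measured, and it may also account for the pattern. Whether a difference in cDNA and cRNA synthesis caused the pattern could not be decided. The 12 spiked poly-A designs, for 4 spike genes, had a median 5' minus 3' difference of 0.0423 (interval -0.0369 to 0.115 over designs). This interval leaves out the spread between arrays and treats designs as independent, though each spike gene has 3. On VH8-4602 replicate 1 the lowest 5' minus 3' signal was -3.33 among the spikes and -4.87 among the cotton transcripts. Whether the spikes respond to a loss towards the 5' end as the cotton transcripts do was not measured. All 12 designs were higher on Guazuncho 2 replicate 1 than on replicate 2. The spike median was 0.27 without Guazuncho 2 replicate 1. It turned to -0.20 without Guazuncho 2 replicate 2 and to -0.09 without VH8-4602 replicate 2, where the cotton medians were -1.10 and -0.72. With each array left out in turn, the cotton median minus the spike median ran from -0.63 to -0.94. The spike median thus never fell as low as the cotton median. Lower integrity of the VH8-4602 RNA may contribute and stays open: it should lower the middle signal too, and the middle minus 3' difference was -0.08 for Ghi-actin and -0.71 for Ghi-ss1 but 0.91 for Gra-actin, with a median of -0.0797. A first test of it only counted how many of the 4 transcripts were lower at the 5' end, which restates the pattern, and was replaced.

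The spiked poly-A controls averaged 8.11 on VH8-4602 replicate 2, against 7.15 on VH8-4602 replicate 1 and 6.99 and 7.25 on the Guazuncho 2 replicates, over 36 probe sets.

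The count of 5791 probe sets cannot be set against chance by regrouping the arrays, since 4 arrays make only 3 splits and the difference between the genotypes enters the residual of the other splits, which lowers their counts. Only the real split, 1 of the 3, gave a count that large, and the highest other count was 0, with 17 and 15 probe sets at an unadjusted p under 0.05 in limma, against 6899 in the real split and 630 that chance alone would give.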
